A study of Mus musculus with 6 samples.

How the data were processed

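The study measured sorted mouse hematopoietic stem cells in 2 fractions of the side population, Lower-SP and Upper-SP, with 3 arrays each. The labels describe 3 pools of mice sorted on separate days, a purity check by running the sorted cells again, and biotin-labeled RNA made with repeated rounds of in vitro transcription. The deposited table holds log2 expression values of 45101 probe sets of an Affymetrix mouse array, summarized by the authors with GCRMA, which corrects background by probe sequence, normalizes the arrays to each other and combines the probes of a set. The submitters' processing notes name GCOS 1.0 and GCRMA without parameters. The values fit that description: near-equal distributions of the 6 columns, a dense band at the bottom and no values under 0. A genome build is not given in the sources used here, and no coordinates are printed. Depth has no equivalent for arrays: 19317 to 19666 probe sets per array lay above log2 4, 17487 on every array, and 23049 lay under it on every array. No column was left out, and 0 pairs of arrays were identical.

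Probe sets were joined to gene symbols with the annotation table supplied for the array: after 64 control probe sets were left out, 34945 of 45037 carried 1 symbol, 932 several and 9160 none, and 34741 of the single-symbol probe sets were matched by Entrez ID to current gene records with 0 symbols needing an update. A probe set was tested if its value was above log2 4 on at least 3 of the 6 arrays (19613, of which 16054 had 1 symbol). Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a trend; two-sided; residual df 4, prior df 3.80), on all 6 arrays, with no replicate block, and p values were adjusted by Benjamini and Hochberg over all tested probe sets, with a threshold of 0.05. A gene was read through its tested single-symbol probe set with the highest mean over the arrays (9460 genes, median SE of the difference 0.235). Before adjustment 8182 probe sets and 3965 genes had p under 0.05. Where a group's mean lay under log2 4, each array under 4 was set to 4 before averaging, and the fold is given as a lower bound.

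In total 26 gene lists were fixed before the data were examined, as were the tests, the filter, the named-gene rule and the alternatives, except where the text says otherwise; 874 of their 942 listed members were matched to an annotated gene. The lists are long-term HSC, multipotent progenitor, megakaryocyte and platelet, erythroid, granulocyte and monocyte, lymphoid priming, mature B cell, mature T and NK cell, mast cell, basophil and eosinophil, endothelial and stromal cell, DNA replication, mitosis, quiescence and cell cycle inhibitor, TGF-beta and BMP pathway, ABC transporter, interferon response, immediate early and stress, Notch pathway, Wnt pathway, Hox cluster and cofactor, adhesion and homing, oxidative phosphorylation, glycolysis, chromatin regulator, apoptosis, and cytokine and growth factor receptor genes. The 24 lists with at least 5 tested members were tested against other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and beside it with camera at an estimated correlation, where 0 lists passed, and with fry. None was chosen on these samples. Some genes stand in several lists.

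The named genes are the 12 most raised and the 12 most lowered genes that passed and whose groups did not overlap; up to 4 passing members of each list with the largest change, or the 2 with the smallest p where fewer than 2 passed; and a fixed set of surface, transporter, TGF-beta pathway and proliferation genes (Slamf1, Cd34, Flt3, Cd48, Procr, Vwf, Abcg2, Abcb1a, Abcb1b, Tgfb1, Tgfbr1, Tgfbr2, Smad2, Smad3, Kit, Ly6a and Mki67). Xist and the Y-linked genes, the further neutrophil genes, the plasma cell genes, the X-linked escape genes, Meg3 and the genes of the 5 added lists were chosen after their values or those of related genes were seen. Of the 12 most raised genes 2, and of the 5 added lists 1, are not reported here.

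Alternatives tried were no filter, a filter at log2 6, a filter on the mean, values under 4 set to 4, no trend, a robust trend, quantile normalization of the deposited values, centring on the median, cyclic loess, array weights, probe sets with names ending in _x_at or _s_at left out, a 2-fold minimum, unmoderated statistics, other representatives of a gene, and each array left out. Added after seeing the data were the omission of Lower-SP replicates 1 and 2 together and the restriction to probe sets annotated to a RefSeq mRNA. The fit was tested on simulated data of 19613 probe sets with 200 changed: 25% of those changed by log2 1 and 70% of those changed by log2 2 were recovered, 3.96% of the calls were unchanged probe sets, the 1 raised list was called and no other, and with nothing changed 0 probe sets and 0 lists were called. The simulated noise was independent between probe sets. On the real arrays the estimated inter-gene correlation of the called lists ran from 0.0091 (chromatin regulator) to 0.37 (mitosis). The simulation therefore cannot vouch for the list calls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.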

Results

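Hematopoietic stem cells were sorted from the bone marrow of 10-week-old male C57Bl/6 (CD45.1) mice as Lineage-negative, Sca-1-positive, c-Kit-positive cells lying in the lower or the upper part of the side population. The side population is a gate on cells that pump out a DNA dye. Each fraction, Lower-SP and Upper-SP, was measured on 3 whole-genome arrays, 1 per biological replicate, and the number of arrays limits the precision. Of 45037 probe sets, 19613 had signal above background and were tested. They represent 9460 genes. Arrays correlated at r = 0.952 to 0.991 within a fraction and at 0.911 to 0.938 between fractions (across probe sets). The first principal component, with 60.8% of the variance, separated Lower-SP from Upper-SP. The second, with 19.3%, separated Lower-SP replicate 3 from Lower-SP replicates 1 and 2. All differences are Lower-SP minus Upper-SP on the log2 scale, each group mean is given ± SD with n = 3, and adjusted p values are from limma.

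Lower-SP cells carried less transcript of several genes that mark early progenitors and more of several genes of the TGF-beta and BMP pathway. Flt3, the receptor tyrosine kinase of lymphoid-primed progenitors, fell by 2.22 (SE 0.26, 4.66-fold, adjusted p = 0.0025), from 10.65 ± 0.09 in Upper-SP to 8.43 ± 0.53 in Lower-SP. Cd34, a surface sialomucin of progenitors, fell by 1.41 (SE 0.17, 8.77 ± 0.15 against 10.18 ± 0.24). Pmepa1, a TGF-beta target that restrains SMAD signaling, rose by 1.85 (SE 0.20, 3.61-fold, adjusted p = 0.0022), with 9.99 ± 0.36 against 8.14 ± 0.04 (a dimmer probe set, at 0.50, did not pass). Abcg2, the transporter that performs most of the dye efflux defining the gate, was itself lower in Lower-SP, by -1.04 (SE 0.16, 8.75 ± 0.17 against 9.79 ± 0.08).

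Of the 9460 tested genes 2625 changed, 667 higher and 1958 lower in Lower-SP, and 1240 of these by at least 2-fold (394 higher, 846 lower). The counts of list members below are to be read beside these shares of all genes. At the level of probe sets 5520 changed, 2090 higher and 3430 lower. The balance between the directions depended on how the arrays were scaled: 25.4% of the changed genes and 37.9% of the changed probe sets were higher with the deposited scaling, against 40.2% and 51.5% with cyclic loess. Cyclic loess moved the median log2 difference of all genes from -0.24 to -0.12, so the directions of gene groups below are read beside that shift. In 4321 genes (45.7%, against 10% by chance) the 3 Lower-SP values did not overlap the 3 Upper-SP values. The counts of changed genes were 1697 without Lower-SP replicate 1, 1407 without Lower-SP replicate 2, 695 without Upper-SP replicate 1 and 1185 without Upper-SP replicate 2. With Lower-SP replicates 1 and 2 left out together, an alternative chosen after seeing the data because these arrays carry neutrophil transcripts, 1197 changed (409 higher, 788 lower). Of the 110 genes named by the fixed rule that passed, 51 passed without Upper-SP replicate 1, 70 without Upper-SP replicate 2, 80 without Lower-SP replicate 1, 76 without Lower-SP replicate 2 and 54 without Lower-SP replicates 1 and 2 together. With both arrays of number 1 left out 0 passed, with both of number 2, 12, with unmoderated statistics 42 and with no filter 67.

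The direction also depended on the kind of probe set. Of 2687 tested probe sets annotated to a RefSeq mRNA, 97 were higher and 709 lower (median -0.38). Of 13367 named by other sequences, 1329 were higher and 2237 lower (median -0.13), and of 3559 without a single gene symbol, 664 were higher and 484 lower (median 0.06). Among 4076 genes with at least 2 tested probe sets, 143 had probe sets called in opposite directions. Their raised probe sets were dimmer (median level 7.04) than their lowered ones (8.62), and 2.45% against 10.9% of them were annotated to a RefSeq mRNA.

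The genes raised most in Lower-SP fall into neutrophil transcripts and a mixed remainder. Chil3, S100a8, S100a9 and Lcn2, genes of abundant neutrophil proteins, rose by 4.65, 4.17, 3.90 and 3.84 (Chil3 at least 14.4-fold and Lcn2 at least 8.80-fold, since Upper-SP lay under the level for testing). Their signal was highest in Lower-SP replicates 1 and 2: S100a8 read 13.2, 12.6 and 9.16 on the 3 Lower-SP arrays and 7.62, 7.87 and 6.95 on the Upper-SP arrays. With Lower-SP replicates 1 and 2 left out, S100a8, S100a9 and Lcn2 did not pass, while Chil3 did, near background. The other raised genes passed with and without those replicates. They include Zswim6 (4.57), the phospholipid-synthesis gene Selenoi (3.73, at least 10.4-fold, with 0.98 at another probe set, not passing), the imprinted noncoding RNA Rian (3.58, at least 7.74-fold), Fam222b (3.54, at least 8.15-fold), the metalloprotease Adamts6 (3.34, at least 3.60-fold) and Cttnbp2nl (3.22).

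Igha, the constant region of the immunoglobulin A heavy chain, fell by 4.42 (SE 1.12, 7.70 ± 2.60 against 12.11 ± 0.70), the most of the genes named by the fixed rule. Its Lower-SP arrays read 9.40, 8.99 and 4.70. Jchain, the immunoglobulin joining chain of plasma cells, followed the same arrays (5.56, 5.16 and 2.38 against 6.08, 6.59 and 5.89 in Upper-SP) without passing, and the plasma cell genes Mzb1, Tnfrsf17, Derl3 and Pou2af1 stayed under the level for testing on every array. Of the plasma cell genes also made by other cells, Xbp1 differed by -0.28 at its brightest probe set and was called lower at another (-0.84), and Sdc1 (-0.07) and Sec11c (-0.02) did not pass. Igha was followed by Dnhd1 (-2.82), Srek1ip1 (-2.79, at least 4.35-fold), the aldo-keto reductase Akr1e1 (-2.70), A830010M20Rik (-2.69, at least 2.89-fold), Nemp2 (-2.68, at least 3.25-fold) and Dnajc27 (-2.63), then the iron-sulfur cluster co-chaperone Hscb (-2.52), Cyp4f13 (-2.46, at least 4.55-fold), the calmodulin-dependent kinase Camk2a (-2.42), AW011738 (-2.40) and the stress kinase Map3k20 (-2.39). A second tested probe set differed by 0.18 for Srek1ip1 and by 0.48 for AW011738, neither of which passed.

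Of 15 tested multipotent progenitor genes, 7 were lower and 1 higher with every scaling tried (8 lower, 1 higher when adjusted over the list alone), with a median of -0.96. Besides Flt3 and Cd34, the lowered members included the costimulatory receptor Tnfrsf18 (-1.57) and the basigin-family gene Emb (-1.43, with -0.34 at another probe set). Satb1, a chromatin organizer of lymphoid progenitors, rose by 1.87 at its brightest probe set, while another of its probe sets fell by 0.73. Its remaining tested probe sets, at -0.52, 0.20 and -0.44, did not pass. As a set the list did not pass against other genes (camera, adjusted p = 0.55). Cd48, a surface marker of restricted progenitors, stayed under the level for testing on every array (highest 2.83), and Ly6a, the gene of Sca-1, was not analysed here.

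Long-term stem cell genes went both ways. Of 28 tested, 2 were higher and 5 lower (1 and 4 when adjusted over the list alone), a balance that became 4 and 4 with cyclic loess. Gfi1 (-1.92), a repressor that restrains stem cell division, the guidance receptor Robo4 (-1.33), Mycn (-1.04) and the stem cell factor receptor Kit (-0.92, SE 0.20, with -0.043 at another probe set) fell, and the catenin-like gene Ctnnal1 (1.44) rose. Mycn did not pass with cyclic loess, quantile normalization or centring. Slamf1, the CD150 gene used to divide the stem cell pool, read 4.72 ± 0.24 against 4.76 ± 0.76 (difference -0.05, adjusted p = 0.94), near the lowest level tested. Procr, the endothelial protein C receptor, read 13.68 ± 0.14 against 13.73 ± 0.11. Both differences were smaller than the SD, and both turned positive with centring (0.042 for Slamf1, 0.038 for Procr). The list's median was -0.07 (0.02 with centring) and its mean -0.18, whereas camera placed it above other genes (adjusted p = 0.80).

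**Figure D1:**
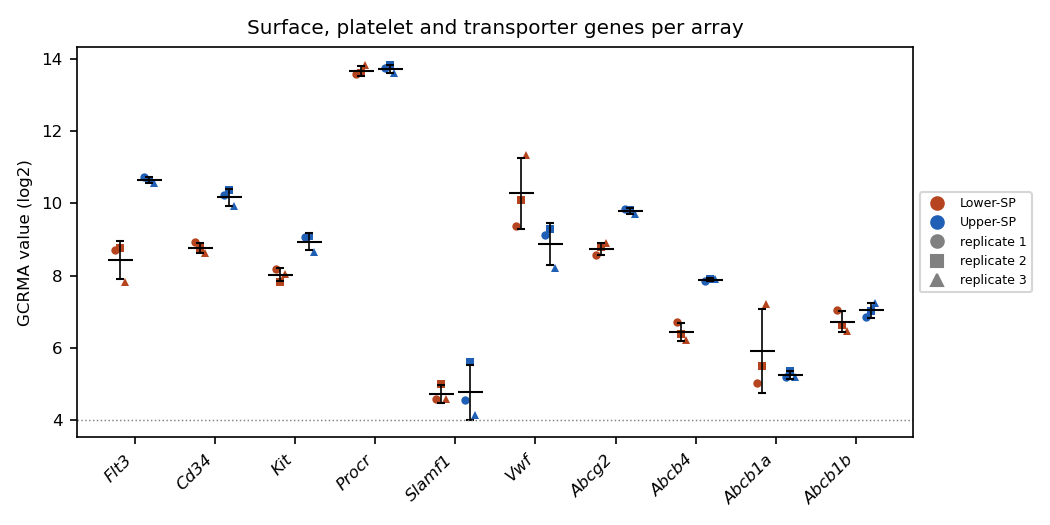
GCRMA values (log2) of surface, platelet and transporter genes on each array: points are the 3 Lower-SP and 3 Upper-SP replicates, black bars the mean ± SD, and the dotted line at 4 the level a probe set had to exceed to be tested. Flt3 and Cd34 lie at 8.43 and 8.77 on average in Lower-SP and at 10.65 and 10.18 in Upper-SP, while the Procr and Slamf1 values of the fractions overlap.

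Of 22 tested ABC transporter genes, 2 were higher and 6 lower (2 and 6 when adjusted over the list alone, 2 and 5 with cyclic loess), with a median of -0.30. The lipid transporter Abca2 (-1.81), the phospholipid floppase Abcb4 (-1.46), Abcg2 and Abcg3 (-1.04) fell. The multidrug transporters Abcb1a (0.67, 5.91 ± 1.16 against 5.24 ± 0.10) and Abcb1b (-0.32) did not pass. Against other genes the list did not pass (camera, adjusted p = 0.88).

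Among lineage genes, 18 tested megakaryocyte and platelet genes included 4 higher and 2 lower (4 and 2 when adjusted over the list alone, 6 and 1 with cyclic loess). The chaperone gene Clu (2.18, SE 0.50) and the platelet receptor chains Gp1bb (1.66, at least 1.59-fold) and Itgb3 (1.41) rose. The urea transporter Slc14a1 fell by 0.83, a call lost with cyclic loess and centring. Vwf, the von Willebrand factor carried by platelet-biased stem cells, read 10.28 ± 0.99 against 8.88 ± 0.58 (difference 1.40, adjusted p = 0.069). It passed with cyclic loess and with quantile normalization, and its adjusted p ranged from 0.026 to 0.22 over its alternatives. The list's median (-0.22) and mean (0.15) differ in sign, and camera placed it above other genes (adjusted p = 0.55). Clu and Itgb3 did not pass with Lower-SP replicates 1 and 2 left out, where Vwf did (2.46, from Lower-SP replicate 3 alone). Vwf read 9.39, 10.1 and 11.3 on the Lower-SP arrays, and without replicate 3 of Lower-SP its difference was 0.86 (adjusted p = 0.11).

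Of 20 tested granulocyte and monocyte genes, 4 were higher and 3 lower (4 and 5 when adjusted over the list alone, 4 and 2 with cyclic loess). S100a8, S100a9 and Lcn2 led, with the macrophage colony-stimulating factor receptor Csf1r (1.06). Without Lower-SP replicates 1 and 2, 0 were higher and 1 was lower. The list averaged 8.64, 8.35 and 7.30 on the Lower-SP arrays and 7.57, 7.62 and 7.02 on the Upper-SP arrays. Its median was -0.20, its mean 0.69, and camera placed it above other genes (adjusted p = 0.67; 0.0088 with RefSeq mRNA probe sets alone, 8 tested).

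Of 16 lymphoid priming genes, 2 were higher and 3 lower (the same counts when adjusted over the list alone, 2 and 2 with cyclic loess). Flt3 and the E protein gene Tcf3 (-1.17) fell. Satb1 (at its brightest probe set, with another called lower) and Tcf4 (0.61, with -0.003 and 0.18 at other probe sets) rose. The median was -0.34, and the list did not pass against other genes (camera, adjusted p = 0.99). Erythroid genes had 2 of 7 lower and 0 higher (3 lower when adjusted over the list alone, 1 with cyclic loess), with a median of -0.16 that turned to 0.04 with cyclic loess (adjusted p = 0.72). The 2 were the heme-binding gene Hebp1 (-1.12) and the biliverdin reductase Blvrb (-0.75, lost with each other scaling).

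Few markers of other mature cells were bright enough to test. Of 10 tested mature B cell genes 3 were lower and 0 higher (3 when adjusted over the list alone, camera adjusted p = 0.73), the tyrosine kinase Btk (-1.74, at least 1.94-fold), the tetraspanin Cd37 (-1.16) and the class II gene H2-Ab1 (-0.68). Of 4 mature T and NK cell genes, the costimulatory receptor Cd28 (-1.34) and the granule gene Nkg7 (-1.14) were lower. Of 3 mast cell, basophil and eosinophil genes, Kit was lower and Srgn, a granule proteoglycan, read 13.97 ± 0.07 against 14.15 ± 0.10 (adjusted p = 0.13). Of 10 endothelial and stromal genes, 1 was lower (1 when adjusted over the list alone, camera adjusted p = 0.91), the matrix protein gene Postn (-2.16, at least 3.19-fold), and the endothelial kinase Tie1 differed by -0.99 (adjusted p = 0.092). Each of these named genes that passed also passed with cyclic loess.

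**Figure D2:**
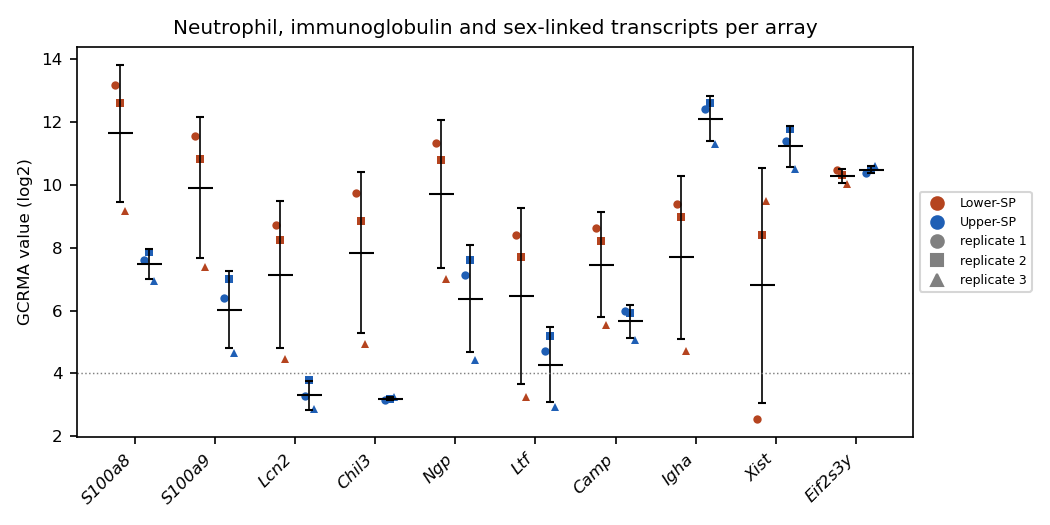
GCRMA values (log2) of neutrophil, immunoglobulin and sex-linked transcripts on each array: points are the 3 Lower-SP and 3 Upper-SP replicates, black bars the mean ± SD, and the dotted line at 4 the level a probe set had to exceed to be tested. S100a8 reads 13.2 and 12.6 in Lower-SP replicates 1 and 2 and 9.16 in replicate 3, and Xist 2.54, 8.39 and 9.49 in Lower-SP against 11.4, 11.8 and 10.5 in Upper-SP.

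TGF-beta and BMP pathway genes lay above other genes as a set. Of 36 tested, 9 were higher and 3 lower (9 and 3 when adjusted over the list alone, 13 and 2 with cyclic loess). The median, 0.16, lay 0.40 above that of all genes (camera, adjusted p = 0.0010). The call was lost with an estimated correlation (adjusted p = 0.51) and by fry, which tests a list against no change (adjusted p = 0.079). The raised members include inhibitors and transducers of the pathway: Pmepa1, the inhibitory Smad6 (1.68, SE 0.49), the BMP transducer Smad1 (1.40, SE 0.27, with 0.36 at another probe set) and the ligand Tgfb1 (0.93, SE 0.23), of which another probe set differed by 0.11. The co-receptor Tgfbr3 fell by 1.04. The TGF-beta transducer Smad2 fell by 0.95 at its brightest probe set, a call lost with cyclic loess and centring, while another of its probe sets was called 1.59 higher. The receptors Tgfbr1 (0.50) and Tgfbr2 (-0.31) and the transducer Smad3 (0.07) did not pass. The list averaged 8.291, 8.215 and 8.459 on the Lower-SP arrays and 8.154, 8.152 and 7.998 on the Upper-SP arrays. The set call was kept with Lower-SP replicates 1 and 2 left out. That fit rests on Lower-SP replicate 3 alone, the array with the highest average, so it cannot show that the call is independent of single arrays. The call was lost with RefSeq mRNA probe sets alone (adjusted p = 0.38, 2 of 11 higher, 3 lower). Its adjusted p ranged from 8.79e-05 to 0.51 over the alternatives.

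**Figure D3:**
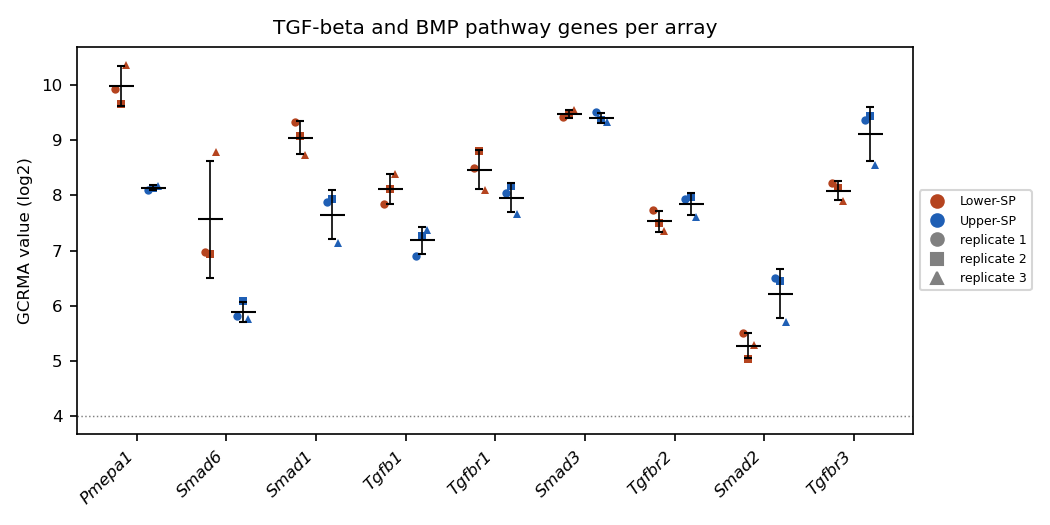
GCRMA values (log2) of TGF-beta and BMP pathway genes on each array: points are the 3 Lower-SP and 3 Upper-SP replicates, black bars the mean ± SD, and the dotted line at 4 the level a probe set had to exceed to be tested. Pmepa1, Smad6, Smad1 and Tgfb1 lie higher in each Lower-SP array than in each Upper-SP array, Smad2 and Tgfbr3 lower, and the Smad3 values of the fractions overlap.

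Mitosis and DNA replication genes lay above other genes as sets in Lower-SP, on arrays that also carry neutrophil transcripts. Of 43 mitosis genes 5 were higher and 1 lower (4 and 1 when adjusted over the list alone, 5 and 0 with cyclic loess), with a median of 0.32 (camera, adjusted p = 0.00014). The call was lost with an estimated correlation (adjusted p = 0.92) and by fry (0.33). Raised members were the condensin subunits Ncapg (2.77, SE 0.41) and Ncaph (1.51), the kinesin Kif2c (2.00; other probe sets of Ncapg, at 0.75, and Kif2c, at 0.50, did not pass) and the cytokinesis scaffold Anln (1.97, lost with cyclic loess and quantile normalization). Of 44 replication genes 4 were higher and 2 lower (1 and 1 when adjusted over the list alone, 7 and 1 with cyclic loess), with a median of 0.14 (adjusted p = 0.0029). This call too was lost with an estimated correlation (adjusted p = 0.92) and by fry (0.36). The ribonucleotide reductase gene Rrm2 (1.18), the origin-firing kinase Cdc7 (1.16) and the licensing factor Cdc6 (0.81) rose, and the histone mRNA-binding gene Slbp fell by 1.19, with 0.02 at another of its probe sets. Mki67, the Ki-67 proliferation antigen, read 10.27 ± 1.35 against 9.52 ± 0.15 (adjusted p = 0.36). Mitosis genes averaged 8.03, 7.85 and 7.13 on the Lower-SP arrays and 7.35, 7.31 and 7.03 on the Upper-SP arrays, with the highest averages in the same Lower-SP replicates as S100a8. Without replicates 1 and 2, the adjusted p was 0.79 for mitosis (1 higher, 3 lower) and 0.57 for replication (0 higher, 2 lower). The replication call was also lost with no filter, without _x_at and _s_at probe sets, with RefSeq mRNA probe sets alone, with either other choice of representative, without Lower-SP replicate 1 (adjusted p = 0.075) and without both arrays of number 1 (0.070). Over the alternatives the adjusted p ranged from 3.94e-10 to 0.92 for mitosis and from 4.24e-05 to 0.92 for replication.

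Quiescence and cell cycle inhibitor genes had 2 of 31 higher and 5 lower (2 and 5 when adjusted over the list alone, 4 and 5 with cyclic loess). The median was -0.11, turning to 0.01 with cyclic loess, and camera placed the list above other genes (adjusted p = 0.80). Gfi1, the antiproliferative gene Btg2 (-1.89) and the thioredoxin inhibitor Txnip (-1.03) fell, and the transcription factor Foxo1, of the forkhead family, rose by 1.21.

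Chromatin regulator genes lay above other genes as a set. Of 42 tested, 11 were higher and 4 lower (11 and 6 when adjusted over the list alone, 13 and 2 with cyclic loess), with a median of 0.06 (camera, adjusted p = 0.016). The call was lost with an estimated correlation (adjusted p = 0.51). Satb1 (at its brightest probe set, with another called lower), the histone H3K4 demethylase Kdm5a (1.80, SE 0.22) and the Polycomb cofactor Jarid2 (1.78, SE 0.18) rose. The H3K9 methyltransferase Ehmt2 fell by 1.71. It was also lost with Lower-SP replicates 1 and 2 left out (adjusted p = 0.29, 8 higher, 3 lower), with no filter, without _x_at and _s_at probe sets, with RefSeq mRNA probe sets alone and with either other choice of representative. The adjusted p ranged from 0.0069 to 0.54 over the alternatives.

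Immediate early and stress genes split, with 9 of 43 higher and 6 lower (9 and 7 when adjusted over the list alone, 12 and 6 with cyclic loess). Their median was -0.02 and their mean 0.06, and camera placed them above other genes (adjusted p = 0.061). The nuclear NF-kappa-B inhibitor Nfkbiz (1.83, with 0.70 at another probe set) and the ERK phosphatase Dusp5 (1.35) rose, while Btg2 and the AP-1 gene Fosl2 (-1.28, with 0.59 at another of its probe sets) fell. This set passed in 8 of 28 alternatives, with cyclic loess at the lower end (adjusted p = 0.027) of a range of 0.027 to 0.52.

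**Figure D4:**
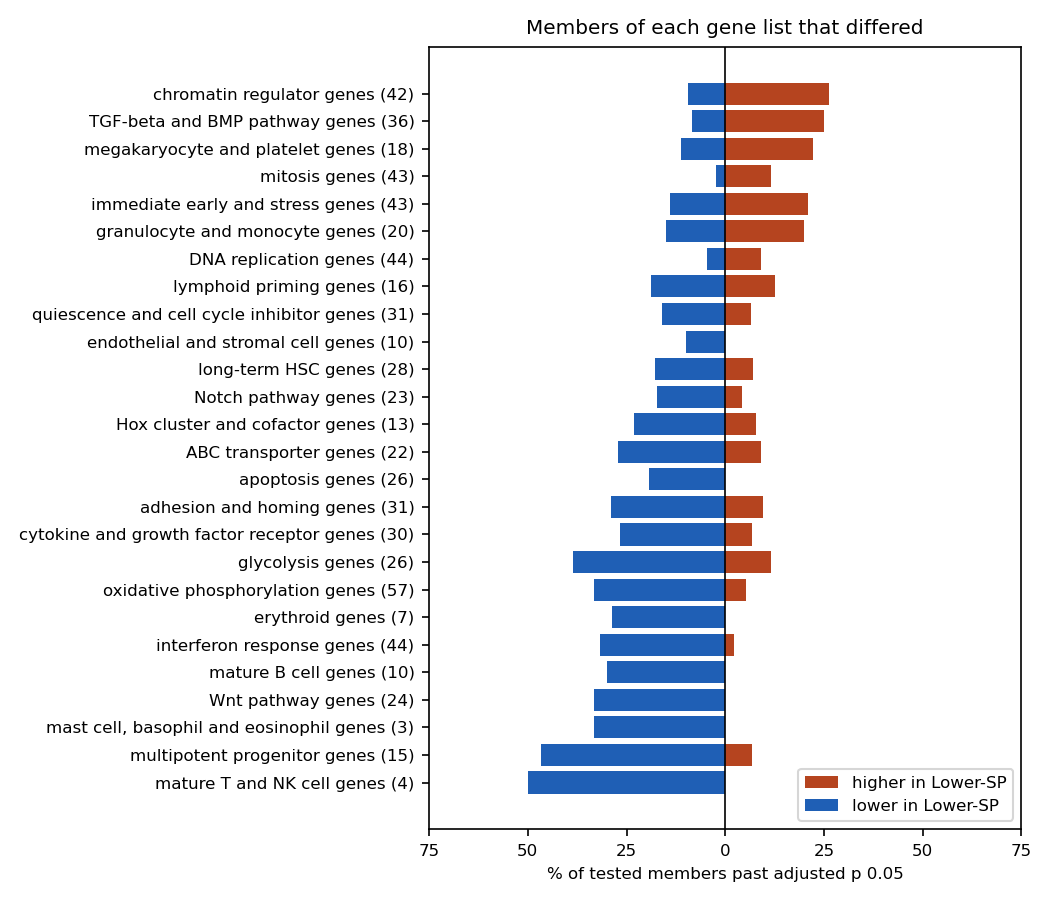
Share of the tested members of each fixed gene list (number tested in parentheses) that were higher (red, to the right of 0) or lower (blue, to the left) in Lower-SP, in % of tested members, at adjusted p under 0.05. Chromatin regulator genes (11 of 42 higher) and TGF-beta and BMP pathway genes (9 of 36 higher) lie at the upper end and multipotent progenitor genes (7 of 15 lower) near the lower end, while glycolysis genes, shown with 3 higher and 10 lower, have 4 and 4 with cyclic loess, and long-term HSC genes 4 and 4.

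The interferon response genes that changed were mostly lower, with 1 of 44 higher and 14 lower (1 and 14 when adjusted over the list alone, 2 and 8 with cyclic loess) and a median of -0.37 (camera, adjusted p = 0.14). Against other genes the list passed with no filter alone (adjusted p = 4.67e-05). The antiviral synthetases Oas2 (-1.43), Oas1a (-1.21, SE 0.17) and Oasl2 (-1.18) fell, and so did the double-stranded RNA kinase Eif2ak2 (-1.52), of which another probe set was called 1.10 higher. Without Lower-SP replicates 1 and 2, 0 were higher and 3 lower.

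Among energy metabolism genes that changed, more were lower than higher with the deposited scaling, and neither list passed against other genes with the fixed filter and representatives. Of 57 oxidative phosphorylation genes, 3 were higher and 19 lower (5 and 22 when adjusted over the list alone, 7 and 10 with cyclic loess), with a median of -0.31 (camera, adjusted p = 0.66). This list passed with no filter (adjusted p = 0.0012) and with the probe set of largest variance (0.035). The complex II subunit Sdhc (-1.40, with -0.21 at another probe set), the ATP synthase subunit Atp5o (-1.05, lost with cyclic loess, with -0.14 at another) and the complex I subunit Ndufs3 (-0.90) fell, and Ndufa5 rose by 1.11 (0.37 at another probe set). Of 26 glycolysis genes, 3 were higher and 10 lower (4 and 12 when adjusted over the list alone), which became 4 and 4 with cyclic loess (median -0.45, adjusted p = 0.67). The phosphofructokinase Pfkm (-1.25) and the hexokinase Hk2 (-1.24, SE 0.18) fell, and the pyruvate dehydrogenase kinase Pdk4 (1.08) and Bpgm (1.12) rose.

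Cytokine and growth factor receptor genes had 2 of 30 higher and 8 lower (2 and 8 when adjusted over the list alone, 2 and 7 with cyclic loess), with a median of -0.31 (camera, adjusted p = 0.66). The interleukin-1 receptor Il1r1 (-2.38, SE 0.30), Tnfrsf1b (-1.30) and Il4ra (-1.24) fell. Adhesion and homing genes had 3 of 31 higher and 9 lower (3 and 9 when adjusted over the list alone, 4 and 9 with cyclic loess), with a median of -0.44 (adjusted p = 0.72). The integrin Itgb5 (-1.64) and the selectin ligand Selplg (-1.41) were lower and the integrin Itga3 (1.58) higher. Of 24 Wnt pathway genes, 8 were lower and 0 higher (8 and 0 when adjusted over the list alone, 6 and 1 with cyclic loess), with a median of -0.12 (adjusted p = 0.88). They include the beta-catenin cofactor Bcl9 (-1.46), the receptor Fzd7 (-1.45), Tcf7l2 (-0.94, at least 1.62-fold, lost with centring, with another probe set not passing) and the cyclin Ccnd1 (-0.88, with 0.30 and -0.11 at other probe sets).

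Of 23 Notch pathway genes, 1 was higher and 4 lower (1 and 3 when adjusted over the list alone, 2 and 3 with cyclic loess). The presenilin Psen2 (-1.01), the target Hey1 (-0.85) and the receptor Notch2 (-0.84, lost with each other scaling) fell and Dtx2 (0.99, with 0.08 at another probe set) rose. The median was -0.17 while camera placed the list above other genes (adjusted p = 0.80). Of 13 Hox cluster and cofactor genes, 1 was higher and 3 lower (1 and 3 when adjusted over the list alone, 2 and 3 with cyclic loess). Hoxa7 (-1.39), Hoxa5 (-0.78, with 0.06 at another probe set) and Hoxa9 (-0.48) were lower and Hoxb3 (1.03) higher, and the median was 0.02 (adjusted p = 0.66). Of 26 apoptosis genes, 5 were lower and 0 higher (4 and 0 when adjusted over the list alone, 3 and 1 with cyclic loess), with a median of -0.30 (adjusted p = 0.88). Among them are the p53-induced killer Bbc3 (-1.67), Mdm4 (-0.94, with -0.06 at another probe set) and the caspase genes Casp8 (-0.76, lost with cyclic loess and quantile normalization) and Casp2 (-0.76). By fry, which asks only whether the genes of a list move one way on balance, 8 lists passed. Downward were multipotent progenitor (adjusted p = 0.040), lymphoid priming (0.025), ABC transporter (0.043), interferon response (0.020), oxidative phosphorylation (0.020), apoptosis (0.043) and cytokine receptor genes (0.020). Chromatin regulator genes (0.043) passed upward. Fry does not set a list against the median of all genes, -0.24, so a downward pass need not be particular to a list. In the order given, the medians of the lowered lists differed from that median by -0.73, -0.10, -0.06, -0.13, -0.07, -0.06 and -0.07. That of chromatin regulator genes differed by 0.30.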

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

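The omission of Lower-SP replicates 1 and 2 together, the restriction to RefSeq mRNA probe sets and the measure used for gene lists here (the mean moderated t of a list's genes minus that of the other tested genes; for fry, the mean t of the list itself) were chosen after the results were seen. With 3 arrays per fraction, signal near background (values under log2 4) limits what can be tested, and the counts depend on single arrays. Across all alternatives the gene lists kept their side of the threshold and direction in 593 comparisons, became weaker in 23, stronger in 19 and reversed in 34; the named genes did so in 2498, 632, 15 and 22. Except where the construction shows it (fewer arrays, more or fewer probe sets tested, a stricter threshold), the cause was not tested.

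Counts are of probe sets, then of genes, with those higher and lower in parentheses. No filter gave 2931 (1252, 1679) and 1318 (386, 932); array weights 10728 (3749, 6979) and 5268 (1301, 3967); a 2-fold minimum 3039 (lower 1577) and 1240 (394, 846); unmoderated statistics 1967 (851, 1116) and 892 (269, 623); Lower-SP replicates 1 and 2 left out 2715 (1191, 1524) and 1197 (409, 788); RefSeq mRNA probe sets alone 873 (101, 772) and 739 (88, 651). Leaving out 1 array, or the 2 arrays of 1 number, gave 0 to 8331 probe sets (0 to 2922 higher, 0 to 5409 lower) and 0 to 4125 genes (0 to 987, 0 to 3138). By array, 1666 probe sets passed without Upper-SP replicate 1, 2623 without Upper-SP replicate 2 and 3114 without Lower-SP replicate 2, and 2253 were lower without Lower-SP replicate 1; without both arrays of number 1, 0 passed (limma; 4667 at unadjusted p under 0.05), of number 2, 202 (63 genes), and of number 3, 8331. The alternatives not named here moved none of these counts by more than 1.5 times. With Lower-SP replicates 1 and 2 left out, the lone Lower-SP array is assumed to vary like the Upper-SP arrays. Of the 2625 genes, 2029 also passed with cyclic loess and 1279 with no filter, none in the other direction. The direction did reverse where another probe set stood for the gene, in 155 of the 2625 with the probe set of largest variance, 103 with the mean of probe sets, 45 without _x_at and _s_at probe sets and 35 with RefSeq mRNA probe sets alone, where 708 were tested.

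The 4 gene lists called became 2 without _x_at and _s_at probe sets, 2 with the mean of a gene's probe sets, 2 with RefSeq mRNA probe sets alone, 1 with Lower-SP replicates 1 and 2 left out, 0 with an estimated correlation, 8 by fry, and 3 to 5 when an array or a number was left out. The labels do not say that a number marks a shared pool. Deviations from the group mean correlated at -0.051, -0.029 and -0.023 between arrays of the same number and at most 0.020, 0.023 and 0.036 between different numbers. With the number as a fixed block 4180 probe sets and 1928 genes passed (1821 of the 2625), and 5 lists, the immediate early genes in addition. Of the 110 genes named by the fixed rule that passed, 94 kept their call with this block. With a random block 5265 probe sets, 2509 genes and 4 lists passed, and 107 of the 110.

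Reversed values, as the list measure or the log2 difference of a gene, were as follows. No filter: long-term HSC -0.487, erythroid 0.0709, lymphoid priming 0.261, quiescence -0.351, Notch -0.0778. Filter at log2 6: endothelial 0.0966. Quantile: lymphoid priming 0.0769, Procr 0.0335. Centred: Slamf1 0.042, Procr 0.038. Cyclic loess: lymphoid priming 0.0737, Srgn 0.00816, Procr 0.15. Array weights: Slamf1 0.16, Smad3 -0.0321. Without _x_at and _s_at: quiescence -0.0605, Notch -0.0563, apoptosis 0.165, Srek1ip1 0.18. Probe set of largest variance: long-term HSC -0.291, apoptosis 0.0217, Smad2 1.59. Mean of probe sets: long-term HSC -0.0683, apoptosis 0.0103, Smad2 0.32. Lower-SP replicates 1 and 2 left out: Wnt 0.304, Procr 0.11, Mki67 -0.79. RefSeq mRNA alone: quiescence -0.246, Wnt 0.579, apoptosis 0.967, Srek1ip1 0.18, Slbp 0.02, Fosl2 0.59. Fry: long-term HSC -0.641, granulocyte and monocyte -0.269, quiescence -0.573, Notch -0.719, Hox -0.584. When an array or a number was left out, these ranges crossed 0: long-term HSC -0.0118 to 0.339, erythroid -1.33 to 0.435, lymphoid priming -0.335 to 0.188, mature B cell -1.49 to 0.665, Notch -0.00597 to 0.527, apoptosis -0.325 to 0.0360, Slamf1 -0.36 to 0.38, Procr -0.19 to 0.041 and Abcb1a -0.0115 to 1.12.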

Other observations

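The tests of the B1 repeat, of the opposite calls and their gap after cyclic loess and of other splits of the arrays, the gene lists of the next paragraph, and the setting of values under log2 4 to 4 in the Xist and neutrophil tests were chosen after the results were seen; the other tests below were written down before the values they measure were seen, though after the patterns themselves were noticed.

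Imprinted genes moved both ways: of 19 tested, 3 were higher and 5 lower (3 and 2 with cyclic loess), Rian (at least 7.74-fold), the zinc finger gene Plagl1 (2.72) and Impact (0.92, with another probe set called lower) up, and the sarcoglycan Sgce (-1.43) and Phlda2 (-1.03) among those down. Meg3, the noncoding RNA of the same imprinted locus as Rian, did not pass at 6 of its 8 tested probe sets, the 3 brightest among them (0.25, -0.23 and -0.67), while 2 dimmer ones rose, the brighter of them by 3.18. Cytosolic ribosomal protein genes had 0 of 36 higher and 12 lower, which became 5 and 2 with cyclic loess; mitochondrial ribosomal protein genes had 1 of 72 higher and 11 lower (2 and 7); and proteasome genes 1 of 32 higher and 6 lower (6 and 2). None of these 4 lists passed against other genes (camera, p adjusted over the 5 added lists, from 0.63 to 0.71). By fry the cytosolic ribosomal, mitochondrial ribosomal and proteasome genes passed downward (adjusted p = 0.021 each). That test is against no change and not against the median of all genes.

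Xist, the RNA of the inactive X chromosome, was high in Upper-SP although the mice are labeled male: its brightest probe set read 11.4, 11.8 and 10.5 in Upper-SP and 2.54, 8.39 and 9.49 in Lower-SP (difference -4.43, adjusted p = 0.070 in limma), and its other 2 tested probe sets passed (-5.21, adjusted p = 0.015, and a dimmer one under log2 4 in Lower-SP, adjusted p = 0.0053). A single misbehaving probe set is argued against, since these 2 passed and, with arrays under 4 set to 4, differed by -4.52 and -0.71 (median -2.61). Upper-SP RNA wholly from female mice is also argued against, since the 2 tested Y-linked genes, Eif2s3y and Uty, averaged at least 7.47 on each Upper-SP array. That average rests on Eif2s3y, which read 10.4, 10.5 and 10.6 in Upper-SP, while Uty read 4.57, 4.47 and 4.88 at its brighter probe set. The Y-linked gene Kdm5d stayed under log2 4 on every array of both fractions. A share of female cells in the Upper-SP samples may remain: the median difference of Eif2s3y and Uty was 0.49 log2, but none of their tested probe sets passed (Eif2s3y -0.21, Uty 1.19 at the brighter of its 2), so 2 genes cannot decide it. The comparison also takes Lower-SP as its baseline, where Xist read 8.39 and 9.49 in replicates 2 and 3, so it cannot confine the question to Upper-SP. On the Lower-SP arrays Uty read 6.3, 6.2 and 4.9 at that probe set, and Eif2s3y 10.5, 10.3 and 10.0. X-linked genes that escape inactivation moved apart: Eif2s3x was called lower in Lower-SP at 2 of 3 tested probe sets (-1.04 and -0.70), Kdm6a higher at 3 of 4 (1.54 at the brightest) and Kdm5c higher at 2 of 6 (1.29 and 2.56). No biological explanation was tested.

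Neutrophil transcripts were higher in Lower-SP replicates 1 and 2 than in replicate 3. Some were also lowest in replicate 3 of Upper-SP: Ngp read 7.1, 7.6 and 4.4 there, Ltf 4.7, 5.2 and 2.9, and S100a9 6.4, 7.0 and 4.7. Chil3 read 3.2 on each Upper-SP array. Since the labels do not say that a number marks a shared pool, a source shared by both fractions stays open. A candidate explanation for the Lower-SP pattern is mature neutrophil RNA in Lower-SP replicates 1 and 2. Over 6 tested of 19 mature neutrophil genes, S100a8, S100a9, Lcn2 and Chil3 not among them, the median difference of replicates 1 and 2 from replicate 3 was 1.73 log2 (SD 1.80). It lies between genes that rose (Ngp 4.06, Ltf at least 4.06, Camp 2.88) and genes that hardly did (Anxa1 0.58, Padi4 0.56, Lyz2 0.30). The latter read at least 7.29 in replicate 3. The genes that rose stand in the fixed granulocyte and monocyte list, whose averages also show the pattern, while Anxa1 and Padi4 do not. The filter left out genes bright in those 2 arrays alone. Among the untested neutrophil genes, Hp read 6.9, 6.1 and 2.6 and Mmp8 4.7, 4.8 and 2.3 on the Lower-SP arrays. Mmp9 reached 4.4 in replicate 1 alone. Cxcr2, Itgam, Il1b, Cd177 and Wfdc21 stayed under log2 4 on every array. Granulocyte progenitors in the same samples cannot be told apart from their absence by the 5 tested of 10 progenitor genes. Their median was 0.078 (SD 0.43), under the bound of 0.5 set beforehand but not by more than the spread. The condition on the spread was added after the value was seen. The high levels of Prtn3 and Calr could hide a small share. Of the untested progenitor genes, Elane, Ctsg, Ms4a3 and Cebpa stayed under log2 4 on every array. Mpo read 4.2, 3.6 and 2.3 on the Lower-SP arrays. Of the 19 neutrophil genes 10 stand in a fixed list and 5 were above log2 4 on every Upper-SP array (9 and 5 of the 10 progenitor genes), S100a8 reached 13.2, the Lineage-negative gate would remove mature neutrophils, and a change in the stem cells of those replicates was not tested.

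The probe sets of 143 genes called in opposite directions were weighed against 3 technical explanations. The scaling between arrays is argued against as the whole cause of the gap between the raised and lowered probe sets, since cyclic loess took its median from 2.24 log2 (SD 0.78) to 2.20 (SD 0.77). Its part in the calls stays open: after cyclic loess 98 of the 143 were still called in opposite directions, between the bounds set for this test, and why the other calls ended was not tested. Unspliced or genomic repeat-bearing RNA more abundant in Lower-SP may account for part of it: the control probe set for the B1 repeat was higher in each Lower-SP array than in each Upper-SP array, by 0.93 log2 (14.8 ± 0.159 against 13.9 ± 0.602). A difference in RNA integrity or amplified length stays open, since the 3' minus 5' signal of Gapdh differed by 0.55 log2, that of Actb by -0.003, between the bounds set beforehand. The Gapdh values of the fractions did not overlap (6.60 ± 0.34 in Lower-SP against 6.05 ± 0.18), while those of Actb did (7.38 ± 0.31 against 7.39 ± 0.18). A difference in transcript forms between the fractions was not tested.

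The 6 arrays make 10 splits into 3 and 3, which cannot give a share under 0.05. The real split gave 5520 probe sets, 2625 genes and 4 gene lists, and the highest other split 0, 0 and 5; as many were reached by 1, 1 and 2 of the 10 splits, and the split with 5 lists set Lower-SP replicates 1 and 2 with Upper-SP replicate 1 against the rest.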
